A study of Rattus norvegicus with 6 samples.

How the data were processed

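Liver total RNA of 6 rats was measured on Agilent 1-colour arrays labelled with Cy3, 1 array per animal: 3 animals given corn oil and 3 given TBBC at 300 mg/kg/day. The labels speak of separate animals, so the p-values measure the spread between animals of a group. Housing, RNA preparation, labelling, hybridisation and scanning add to it where they differ within a group. A difference shared by all arrays of a group, such as that of slide and scan, is not part of that spread. Age at purchase was 5 weeks, per the labels' protocols.

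The deposited files are scanner output whose values are spot intensity on a linear scale. Per the file headers, the authors extracted them with Agilent Feature Extraction 10.7.1.1 (version 10.7 per the submitters' processing notes), which subtracts background and writes a processed intensity for each spot. The files also hold median pixel and background intensity, a flag for spots well above background, saturation flags and outlier flags. The deposited value table of the series holds 1 intensity value per probe and array. Set against the scanner values, each of its columns was the processed intensity times 1 constant, so that its 75th percentile was 1.0; its scale is linear, its direction is that of the signal and no centring of genes had been applied. The column medians were 0.1013, 0.1077 and 0.1033 for vehicle replicates 1 to 3 and 0.0977, 0.0972 and 0.0974 for TBBC replicates 1 to 3. This table was used as an alternative.

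Each array held 62976 spots, of which 1439 were controls and 61537 were probes spotted once. The 75th percentile of the processed intensity was 577.9, 465.2 and 598.1 on vehicle replicates 1 to 3 and 616.1, 626.5 and 638.2 on TBBC replicates 1 to 3. On those arrays 62.0%, 61.5%, 62.2%, 63.5%, 64.0% and 60.0% of probes were well above background, and 1 to 3 probes were saturated. Control spots were left out, as were 25 probes with an outlier flag on any array. Values were log2 of the processed intensity minus the array's 75th percentile over all probes other than controls. Probes well above background on all arrays of at least 1 group were kept (37222 probes). The scanner files hold accessions but no column of gene names, so probes were named through their unversioned RefSeq accessions in a gene table of the assembly GRCr8. This named 28206 probes (45.8%) with 15645 symbols and left 33331 without a name here. The file headers name the build rn4 for the array design, so no coordinates are given. Each gene was represented by its probe with the highest mean over all 6 arrays, and a probe without a name stood alone, which gave 29326 features (11235 genes and 18091 unnamed probes). Of 171 genes past the threshold with 2 or more retained probes, 8 had a probe with the opposite sign.

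Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Differences are TBBC minus vehicle on the log2 scale with the moderated standard error. A probe not well above background on any array of a group has only a bound there: the bright group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 against all other features, adjusted over the 47 lists, and again with an estimated correlation and with fry. Beside each list stands the number of its members that rose and fell when p-values were adjusted over the list alone; pairs of such numbers give the risers first.

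The design, the lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, leaving out names that are only identifiers and probes not well above background on every array. Of each list it took up to 4 members past the threshold by size of change, or where none passed up to 2 with the highest mean signal. It also took up to 5 genes per direction, by size of the bound, among those measured on all arrays of 1 group and on none of the other. The values of 1 gene that the rule takes are not reported here. The design had assumed a column of gene names and one of mean spot signals; the files hold neither, so accessions were used for names and the planned normexp correction of mean signals was not run.

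Alternatives were quantile normalization, median centring, no filter on dim probes, only probes above background on all 6 arrays, the mean of a gene's probes, the deposited value table, eBayes with trend and robust, array weights, the replicate number as a block, every probe on its own, treat against a log2 difference of 0.5, camera with an estimated correlation, fry, and leaving out each array. After the data were seen, normexp (offset 50) on median spot signals and a scaling on the 8 spike-in control probes above background were added. Slide and scan could not enter a fit, since each slide and scan held 1 group. The procedure was tested on simulated data: 5 sets were drawn for the 29326 features from the measured means and spreads, 3 arrays against 3, with 200 features changed in each. It recovered 2.00% of features changed by 0.5 on the log2 scale, 47.20% of those changed by 1, 75.60% of those changed by 2 and 95.60% of those changed by 4. Of 571 calls, 20 were of unchanged features, and the list shifted by 0.3 was called in all 5 sets with 0 other lists. The 200 changed features per set were fewer than the 902 features past the threshold in the measured data. The adjusted threshold depends on how many features change, so these recovery rates may not hold for the measured comparison. The features were drawn independently of each other. The simulation therefore says nothing about false list calls where the members of a list correlate, as in the measured lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.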

Results

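Liver RNA of 6 male Sprague-Dawley rats was measured on 1-colour oligonucleotide arrays, 1 array per animal. The vehicle group (n = 3) had received corn oil and the treated group (n = 3) had received TBBC, a sulfur-bridged antioxidant made of a pair of tert-butyl-m-cresol units, at 300 mg/kg/day. The labels disagree on the length of dosing: the series text places the measurement at 28 days and the treatment protocol speaks of 9 weeks. Each array carried 61537 probes other than controls. The 75th percentile of their signal lay between 465.2 and 638.2, and between 36919 and 39386 probes per array were well above background. Correlations across all tested features were 0.986 to 0.990 among vehicle arrays, 0.989 to 0.991 among TBBC arrays and 0.975 to 0.984 between the groups. Vehicle replicate 2 had the lowest 75th percentile (465.2) and the widest spread of its spike-in control signals (9.11% against 3.01% to 4.11% on the other arrays). The number of arrays limits the precision of what follows.

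The comparison of TBBC with vehicle asks which liver transcripts differ after repeated dosing with the chemical. With TBBC, the liver held far more RNA for most measured Cyp2b enzymes, inducible enzymes of drug metabolism, and for the efflux transporter Abcc3, which carries glucuronides out of hepatocytes into blood. Transcripts of conjugating enzymes, of cholesterol synthesis and of the proteasome were higher as groups with the preset correlation of camera. With an estimated correlation these calls were lost (glutathione genes adjusted p = 0.50, glucuronidation and sulfation adjusted p = 0.491, cholesterol synthesis adjusted p = 0.581, proteasome adjusted p = 0.528). Transcripts of the liver hormone Fgf21 and of the apolipoprotein Apoa4 fell by large amounts. At an adjusted p under 0.05, 902 of 29326 features changed, 492 of them higher and 410 lower with TBBC, and 502 changed at least 2-fold. Among the 11235 features with a gene name, 356 changed (211 higher, 145 lower), and 203 of these changed at least 2-fold (121 higher, 82 lower). The other 546 features past the threshold were probes with no gene name here. Of the 47 gene lists, 12 were higher and 4 lower with TBBC by camera with its preset correlation, and none was past the threshold with an estimated correlation, where the lowest adjusted p was 0.213.

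The list of drug-metabolism genes induced through the receptors CAR and PXR, nuclear receptors that sense foreign chemicals, held 25 tested members, of which 15 rose, 1 fell and 9 did not pass the test. Adjusted over the list alone, 20 rose and 1 fell. The median log2 difference was 1.44 (camera adjusted p = 7.2e-20; adjusted p = 0.213 with an estimated correlation). Abcc3 rose by 4.96 ± 0.21 on the log2 scale (SE, n = 3 per group), Cyp2b1 by 4.63 ± 0.22, Cyp2b2 by 4.18 ± 0.17 and Cyp2b15 by 3.92 ± 0.23. The member that fell, Cyp2b3, differed by -0.56 ± 0.10 and was singled out after its values were seen. Its call was lost in 11 of 18 settings. Cyp2b12, outside the list, rose by 4.42 ± 0.20. Probes of the Cyp2b genes can bind RNA of more than 1 member of the subfamily, so the value of each single member is uncertain; the 5 probes of Cyp2b2 gave 3.84 to 5.77. The gene with the largest rise among those measured on all 6 arrays was Cyp2c24, a cytochrome of the Cyp2c subfamily, at 8.08 ± 0.77 (271-fold, adjusted p = 0.00895), and its 2 probes gave 8.08 and 8.50. Without vehicle replicate 1 the difference of Cyp2c24 was 7.29, and without TBBC replicate 2 it did not pass (adjusted p = 0.0536).

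**Figure D1:**
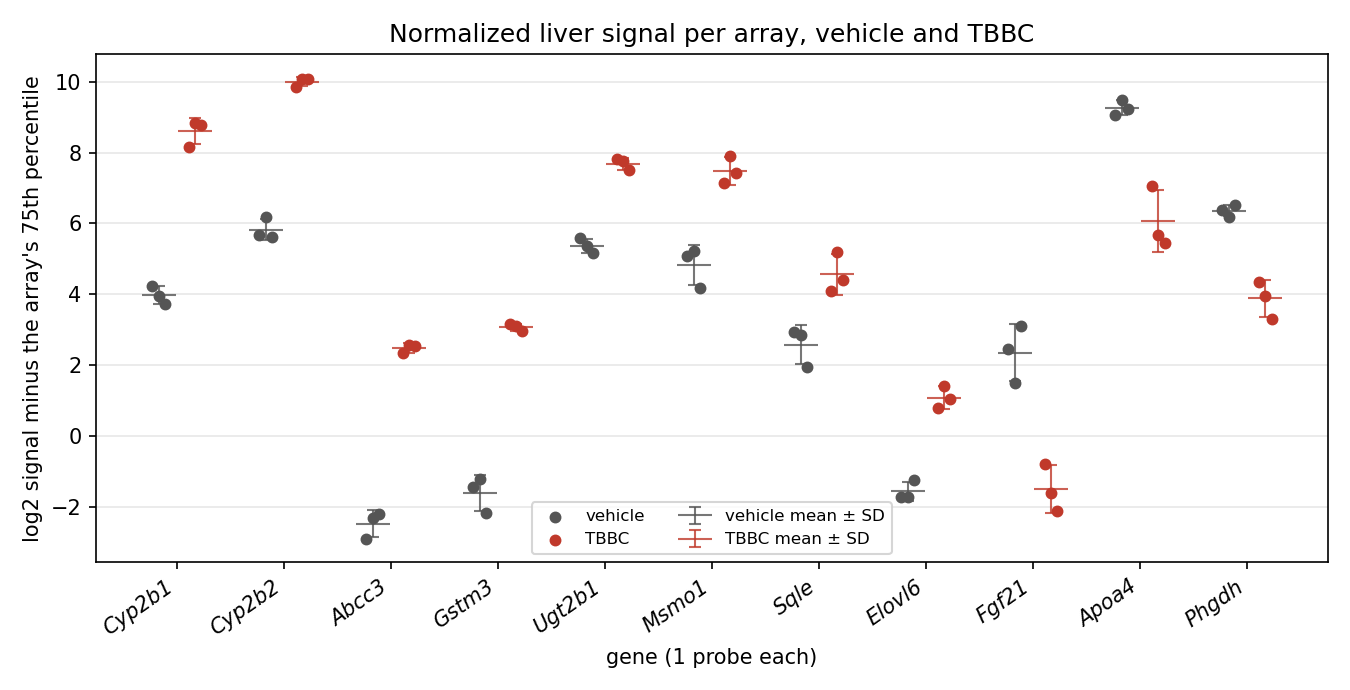
Normalized log2 signal (signal minus the array's 75th percentile, vertical axis) of 11 genes in each vehicle array and each TBBC array (points), with the group mean and SD (bars, n = 3). The vehicle and TBBC points of each gene do not overlap: Cyp2b1, Cyp2b2, Abcc3, Gstm3, Ugt2b1, Msmo1, Sqle and Elovl6 lie higher with TBBC, and Fgf21, Apoa4 and Phgdh lie lower.

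Conjugation enzymes were higher as groups. Of 31 tested genes of glutathione transfer and glutathione metabolism, 7 rose, 0 fell and 24 did not pass the test; adjusted over the list alone, 14 rose and 1 fell. The median was 0.61 (camera adjusted p = 3.2e-08; adjusted p = 0.50 with an estimated correlation). Among the glutathione transferases, Gstm3 rose by 4.69 ± 0.25, Gsta5 by 1.32 ± 0.18 and Gstm1 by 1.13 ± 0.18, and the microsomal Mgst2 by 1.04 ± 0.16. Of 22 genes of glucuronidation and sulfation, 6 rose, 1 fell and 15 did not pass; adjusted over the list alone, 11 rose and 1 fell. This list had a median of 0.58 (camera adjusted p = 1.2e-05; adjusted p = 0.491 with an estimated correlation). The sulfotransferase Sult2a6 rose by 4.91 ± 0.35, the glucuronosyltransferase Ugt2b1 by 2.31 ± 0.15 and Sult2b1 by 2.16 ± 0.28, whereas Sult1c2 fell by 1.60 ± 0.28 on the log2 scale. Sult2a2, not counted in this list, which holds that symbol only as another name of Sult2a1, rose by 4.30 ± 0.66 (3.51 without TBBC replicate 2). As with Cyp2b, probes of Sult2a, Gsta and Ugt2b genes can bind RNA of close relatives, and the 3 probes of Gsta3 gave 0.73 to 2.68.

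Of 31 targets of NRF2, the transcription factor of the antioxidant response, 5 rose, 0 fell and 26 did not pass; adjusted over the list alone, 14 rose and 1 fell. The median was 0.44 (camera adjusted p = 3.5e-06; adjusted p = 0.50 with an estimated correlation). Besides Abcc3 and Gstm1, Ephx1, the microsomal epoxide hydrolase, rose by 1.57 ± 0.14 and Gsta3 by 0.76 ± 0.13. All of these also belong to other lists: Abcc3 and Ephx1 to the CAR and PXR list, Gstm1 and Gsta3 to the glutathione list. Of 7 targets of the aryl hydrocarbon receptor, 2 rose, 0 fell and 5 did not pass; adjusted over the list alone, 4 rose. The median was 0.64, with or without Cyp1a1 set to its bound (camera adjusted p = 0.0305; adjusted p = 0.581 with an estimated correlation). Cyp1a1, the classical target, was not well above background on any vehicle array. It was at least 1.61-fold higher with TBBC, or at least 1.18-fold without TBBC replicate 3. Its limma adjusted p of 0.0379 belongs to the difference from the dim vehicle values, not to the bound, and its call was lost in 8 of 17 settings. Ahr, the receptor itself, rose by 1.05 ± 0.19. This list did not pass without TBBC replicate 2, with quantile normalization or with only probes above background on all 6 arrays (median 0.35), and without a filter on dim probes its median was 0.05. Of 12 genes of haem synthesis and breakdown, 0 rose and 0 fell; adjusted over the list alone, 3 rose. The median was 0.19 (camera adjusted p = 0.0305; adjusted p = 0.581 with an estimated correlation), and the call was lost with quantile normalization and without vehicle replicate 2 (median 0.06), TBBC replicate 1 or TBBC replicate 2. Alas1, the first enzyme of haem synthesis, had a log2 difference of 1.49 ± 0.33 (adjusted p = 0.0690), and Alad one of -0.15 ± 0.15. Of 24 hepatic transporters, 3 rose and 0 fell (5 and 2 adjusted over the list alone, median 0.02, camera adjusted p = 0.148). The 3 were Abcc3, the organic anion carrier Slco1a4 (2.15-fold, adjusted p = 0.0371) and the bile salt export pump Abcb11 (log2 difference 0.95 ± 0.18). The call of Abcb11 was lost in 10 of 18 settings.

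Cholesterol synthesis was higher throughout its list. All 25 tested members had a positive log2 difference, 11 rose, 0 fell and 14 did not pass the test; adjusted over the list alone, 21 rose. The median was 1.18 (camera adjusted p = 3.4e-18; adjusted p = 0.581 with an estimated correlation), and the estimated correlation between members, 0.792, was high. Msmo1, which removes a methyl group from sterol intermediates, rose by 2.66 ± 0.32, the sterol reductase Tm7sf2 by 2.22 ± 0.31, the isoprenoid isomerase Idi1 by 2.07 ± 0.39 and the squalene epoxidase Sqle by 1.99 ± 0.37.

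Fatty acid and triglyceride synthesis did not move as a group: of 23 members, 3 rose, 3 fell and 17 did not pass (5 and 8 adjusted over the list alone; median -0.22, camera adjusted p = 0.781), and the signs of the median and of the test differed. Elovl6, which elongates saturated fatty acids, rose by 2.65 ± 0.21, the acetyl-CoA carboxylase Acacb by 1.73 ± 0.27 and the acetyl-CoA synthetase Acss2 by 1.55 ± 0.21. Acacb was well above background on 2 of 3 vehicle arrays. The glycolytic enzyme Pklr fell by 1.24 ± 0.16 on the log2 scale and the elongase Elovl5 by 0.72 ± 0.12, both named after their values were seen. Of 43 PPAR alpha targets and fatty acid oxidation genes, 4 rose, 1 fell and 38 did not pass (5 and 1 adjusted over the list alone). Their median was 0.06 (camera adjusted p = 0.0280; adjusted p = 0.776 with an estimated correlation), and the call was lost with spike-in scaling (median 0.28) or quantile normalization and without vehicle replicate 2, TBBC replicate 1 or TBBC replicate 3. The fatty acid transporter Cd36 rose by 2.16 ± 0.27 and the peroxisomal enzymes Ehhadh and Acaa1b by 1.44 ± 0.27 and 1.18 ± 0.17, while Fgf21 fell by 3.85 ± 0.48.

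Lipid droplet and lipoprotein genes (25 tested) had 1 riser, Cd36, and 2 that fell, Apoa4 by 3.20 ± 0.42 and Apoc2 by 0.79 ± 0.11 (4 and 5 adjusted over the list alone; camera adjusted p = 0.907). In bile acid synthesis (16 tested), Slc27a5, which activates bile acids for conjugation, rose by 1.29 ± 0.15 and Hsd3b7 by 0.58 ± 0.11, with none lower (3 and 2 adjusted over the list alone; median 0.10, camera adjusted p = 0.373). In gluconeogenesis and the fasting response (19 tested) and in the tricarboxylic acid cycle (21 tested), the pyruvate carboxylase Pc fell by 0.62 ± 0.11 and no other member passed (0 and 2, and 0 and 1, adjusted over the list alone; camera adjusted p = 0.662 and 0.513). Of 36 urea cycle and amino acid genes, Agxt fell by 1.31 ± 0.21 and none rose (0 and 1 adjusted over the list alone; camera adjusted p = 0.253). None of the 67 oxidative phosphorylation genes passed, over the list alone or over all features (median -0.06, camera adjusted p = 0.497); the abundant Atp5f1a and Cox6a1 differed by -0.20 ± 0.12 and -0.05 ± 0.12.

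All 32 proteasome subunits had a positive log2 difference, 3 rose, 0 fell and 29 did not pass the test; adjusted over the list alone, 21 rose. The median was 0.38 (camera adjusted p = 5.9e-16; adjusted p = 0.528 with an estimated correlation). Psmd14 rose by 0.72 ± 0.13, Psma7 by 0.63 ± 0.11 and Psmb6 by 0.59 ± 0.11. Of 17 heat shock chaperones, 0 passed over all features and 8 rose when adjusted over the list alone. Their median was 0.42 (camera adjusted p = 7.1e-07; adjusted p = 0.581 with an estimated correlation), with Hspa8 at 0.42 ± 0.15 and Hspe1 at 0.30 ± 0.14. The 8 retained probes of Hspa8 gave 0.42 to 1.53. None of the 45 cytosolic ribosomal protein genes passed, and 42 of them had a negative log2 difference. Their median was -0.22 (camera adjusted p = 5.0e-05, adjusted p = 0.745 with an estimated correlation). It was 0.00 when arrays were scaled on their spike-in controls, where the list did not pass. That scaling shifts each array as a whole, and relative to the median of all features the list lay at -0.16 in both. Rplp1 differed by -0.29 ± 0.11 and Rplp0 by -0.21 ± 0.11. Of 30 genes of the unfolded protein and integrated stress responses, 0 rose, 4 fell and 26 did not pass; adjusted over the list alone, 5 fell. The median was -0.27 (camera adjusted p = 0.0215, adjusted p = 0.738 with an estimated correlation). The call was lost with normexp and without vehicle replicate 2 or TBBC replicate 1. With spike-in scaling the median was -0.05. Relative to the median of all features it was -0.21, which a shift of whole arrays cannot change. That value was -0.21 with normexp and -0.26 with quantile normalization. The stress-induced transcription factor Atf5 fell by 1.69 ± 0.16, the asparagine synthetase Asns by 1.65 ± 0.24, the stress-response cofactor Nupr1 by 1.47 ± 0.22 and Herpud1, of the degradation machinery of the endoplasmic reticulum, by 1.35 ± 0.21. Phgdh, the first enzyme of serine synthesis, in no list, fell by 2.48 ± 0.26.

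**Figure D2:**
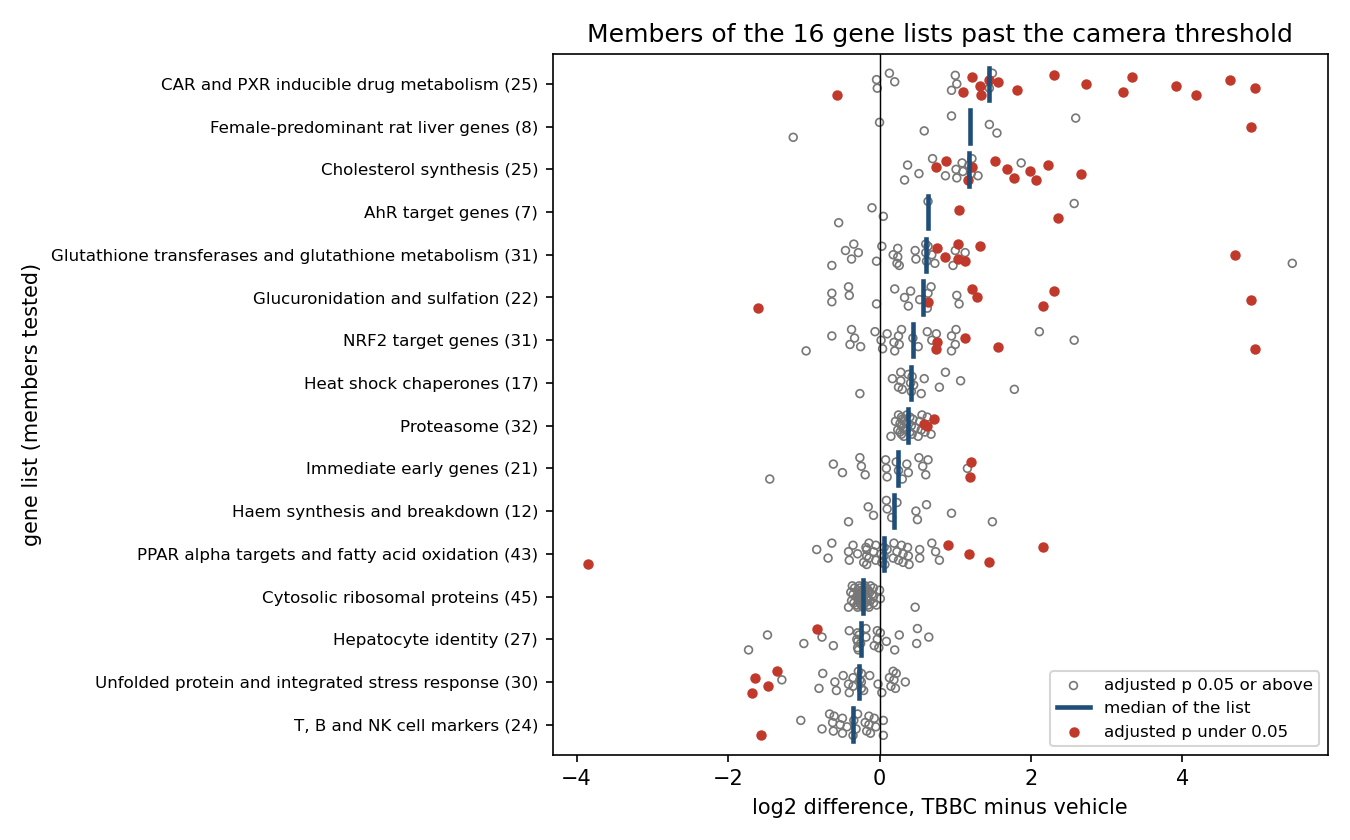
Log2 difference between TBBC and vehicle (horizontal axis) of each tested member of the 16 gene lists past the camera threshold with the preset correlation; filled points have an adjusted p under 0.05 over all features, open points do not, and bars mark list medians. The medians run from -0.35 for T, B and NK cell markers to 1.44 for the CAR and PXR list. That of ribosomal proteins, -0.22 here, is 0.00 under spike-in scaling, which moves all features. Relative to the median of all features it is -0.16 in both.

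Hepatocyte identity genes were lower as a group: of 27 tested, 0 rose, 1 fell and 26 did not pass, and adjusted over the list alone 1 rose and 7 fell. The median was -0.25 (camera adjusted p = 0.0270, adjusted p = 0.581 with an estimated correlation). The call was lost with normexp and without vehicle replicate 1 or vehicle replicate 3. With spike-in scaling, which shifts each array as a whole, the median was -0.03. Relative to the median of all features it was -0.18, a value that such a shift cannot change. That value was -0.06 with normexp and -0.10 with quantile normalization. Ahsg, which encodes the plasma protein fetuin-A, fell by 0.83 ± 0.12. The female-predominant list (8 tested) was higher, with a median of 1.20 (camera adjusted p = 0.00248; adjusted p = 0.566 with an estimated correlation). In that list 1 member rose, Sult2a6, and adjusted over the list alone 5 rose and 1 fell. The female-predominant list shares Sult2a6 with the glucuronidation and sulfation list, and Cyp2a1 and Cyp3a9 with the CAR and PXR list. None of the 13 male-predominant genes passed (median -0.23, camera adjusted p = 0.662), with Obp3 at -0.23 ± 0.11 and Mup5 at -0.18 ± 0.14. The 2 retained probes of Obp3 gave -1.61 and -0.23, and those of Mup5 -0.35 and -0.18. In the growth hormone and IGF list (16 tested), Stat5a fell by 0.79 ± 0.12 and none rose (1 and 2 adjusted over the list alone; camera adjusted p = 0.191). Of 10 thyroid hormone responsive genes, 2 fell and none rose (2 and 5 adjusted over the list alone, camera adjusted p = 0.191). The mitochondrial glycerol phosphate dehydrogenase Gpd2 fell by 1.58 ± 0.21 and the deiodinase Dio1 by 1.19 ± 0.23. The call of Dio1 was lost in 12 of 18 settings, among them the mean of its probes, and that of Gpd2 in 8. Among 19 pericentral genes, Ahr rose, Rgn fell by 0.91 ± 0.17 and the glutamine synthetase Glul fell by 0.82 ± 0.14 (2 and 3 adjusted over the list alone; camera adjusted p = 0.968). None of 16 periportal genes passed (camera adjusted p = 0.662), with Arg1 at 0.77 ± 0.28 and Pigr at -0.14 ± 0.15. Of 24 acute phase genes, Orm1 rose by 1.49 ± 0.26 and Crp by 0.86 ± 0.13, with none lower, and the same number passed when adjusted over the list alone (camera adjusted p = 0.101). Of 27 complement and coagulation genes, Serpind1 fell by 0.55 ± 0.10 and none rose, over all features and adjusted over the list alone (camera adjusted p = 0.662). The immediate early list (21 tested) was higher, with a median of 0.25 (camera adjusted p = 0.0462; adjusted p = 0.738 with an estimated correlation). Its call was lost with median centring, spike-in scaling (median 0.47), quantile normalization or only probes above background on all 6 arrays, and without vehicle replicate 3, TBBC replicate 1 or TBBC replicate 3. In it Ier3 rose by 1.21 ± 0.18 and Klf6 by 1.19 ± 0.18 (2 and 0 adjusted over the list alone).

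T, B and NK cell markers (24 tested, 22 with a negative log2 difference) were lower, with a median of -0.35 (camera adjusted p = 0.00693, adjusted p = 0.738 with an estimated correlation). With spike-in scaling, a shift of whole arrays, the median was -0.13. Relative to the median of all features it was -0.28, which such a shift cannot change. That value was -0.19 with normexp and -0.29 with quantile normalization. In that list Cd6, a T cell surface protein, fell by 1.57 ± 0.25 and no other member passed, also when adjusted over the list alone. The 2 retained probes of Cd6 gave -1.57 and -0.48. Biliary and ductular markers (15 tested) had 2 risers, Epcam at 1.83 ± 0.21 and Krt8 at 1.43 ± 0.15, and none lower (3 and 0 adjusted over the list alone; median 0.16, camera adjusted p = 0.121). Of 33 stellate cell, fibroblast and matrix genes, Rgs5 rose by 0.95 ± 0.12 and Pdgfrb fell by 0.73 ± 0.14, also when adjusted over the list alone (camera adjusted p = 0.661). None of 25 Kupffer cell and macrophage markers passed (median 0.07, camera adjusted p = 0.662), with Clec4f at -0.02 ± 0.37 and C1qb at -0.07 ± 0.38. The same held for 9 neutrophil markers (camera adjusted p = 0.662; S100a9 at -0.14 ± 0.60 and Np4 at -0.34 ± 0.15, whose 2 probes gave -2.17 and -0.34; 0 and 1 adjusted over the list alone) and for 19 sinusoidal endothelial markers (camera adjusted p = 0.662; Kdr at -0.03 ± 0.22, Fcgr2b at 0.44 ± 0.37). It held too for 9 erythroid and blood markers (camera adjusted p = 0.831; Hba-a1 at 0.08 ± 0.24, Hbb at 0.05 ± 0.21) and for 10 skeletal muscle and adipose markers (camera adjusted p = 0.790; Cfd at 0.11 ± 0.30, Tnni2 at -0.34 ± 0.23). Of 7 pancreatic acinar markers none passed over all features and 1 did adjusted over the list alone (camera adjusted p = 0.413), with Spink1 at 2.10 ± 0.44 (adjusted p = 0.0615) and Ctrb1 at -0.18 ± 0.12.

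Proliferation and inflammation lists held few or no calls. None of 43 cell cycle and DNA replication genes passed, over all features or over the list alone (median -0.18, camera adjusted p = 0.781), with Ccnd1 at -1.21 ± 0.54 and Tacc3 at 0.20 ± 0.19. Of 26 p53 targets and DNA damage genes, Mdm2, the negative regulator of p53, rose by 0.69 ± 0.12 and none fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0948). Of 25 apoptosis mediators, Bmf, a death-promoting member of the Bcl2 family, fell by 2.65 ± 0.48 and none rose, also when adjusted over the list alone (camera adjusted p = 0.753). No member passed among 35 interferon response and antigen presentation genes (camera adjusted p = 0.135; B2m at 0.14 ± 0.11, Ifi27 at 0.35 ± 0.12) or 22 chemokines and inflammatory signalling genes (camera adjusted p = 0.781; Ccl24 at -0.10 ± 0.11, Ccl6 at 0.26 ± 0.44; 1 and 0 adjusted over the list alone). The same was true of 17 fetal liver and preneoplastic focus markers (camera adjusted p = 0.578; Afp at -0.89 ± 0.24, Akr7a3 at 0.75 ± 0.50; 2 and 1 adjusted over the list alone), 21 metal and iron genes (camera adjusted p = 0.781; Tf at -0.29 ± 0.12, Ftl1 at -0.25 ± 0.11) and 16 circadian clock genes (camera adjusted p = 0.781; Dbp at 0.05 ± 0.24, Usp2 at 0.61 ± 0.20).

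Several genes with large changes belonged to none of the lists. Higher with TBBC were the NMDA receptor subunit Grin2c (3.98 ± 0.62; 3.22 without TBBC replicate 3), the dual oxidase maturation factor Duoxa1 (3.52 ± 0.36) and Nol3, an apoptosis repressor (3.42 ± 0.41). The largest fall among genes measured on all 6 arrays was that of Cib2, a calcium-binding protein, at -5.61 ± 0.64 (48.8-fold lower). Prl3d4, of the placental prolactin family, fell by 4.93 ± 0.31. On their brightest probes the transporter Slc30a3 fell by 3.88 ± 0.52 (-3.27 without vehicle replicate 3) and the transporter Slc29a4 fell by 3.56 ± 0.37, but other probes of these genes gave differences as small as -0.67 and -0.40. Acnat2, a peroxisomal acyltransferase, fell by 3.60 ± 0.58 (-2.95 without TBBC replicate 2). Among the fits that left out 1 array, its call held only without TBBC replicate 1. The peptide hormone Adm2 fell by 3.14 ± 0.34 and the olfactory receptor Olr59 by 2.57 ± 0.44. For genes well above background on all 3 arrays of 1 group and on none of the other, only a bound was measured. Ppl was at least 4.15-fold higher with TBBC, Tsx at least 2.58-fold, the amino acid transporter Slc7a5 at least 2.45-fold, Opn3 at least 1.98-fold and Kif26b at least 1.74-fold. Mmd2 was at least 22.2-fold lower (at least 12.5-fold without vehicle replicate 1, and not past the threshold without vehicle replicate 2 or any 1 of the TBBC arrays), Cngb3 at least 18.2-fold and the sialyltransferase St8sia1 at least 3.29-fold.

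All adjusted p-values are from limma with Benjamini-Hochberg adjustment, two-sided. Of the 83 genes named by the rule and past the threshold, 13 stayed past it under every gene-level setting tried that measured them: Abcc3, Cyp2b1, Cyp2b2, Cyp2b12, Cyp2b15, Gstm3, Sult2a6, Ugt2b1, Ephx1, Elovl6, Prl3d4, Cngb3 and St8sia1. Every array mattered for the counts: 137 features passed without vehicle replicate 1, 214 without vehicle replicate 2, 273 without vehicle replicate 3, 365 without TBBC replicate 1, 104 without TBBC replicate 2 and 239 without TBBC replicate 3, and of the 83 genes 24, 27, 32, 41, 18 and 29 passed, in that order. The 3 vehicle arrays shared slide 1 and scan 1 and the 3 TBBC arrays slide 2 and scan 2, so batch and group cannot be told apart; scaling moved the split between higher and lower calls from 492 and 410 to 746 and 306 with median centring and to 574 and 130 on the spike-in controls, where the median log2 difference of all features was 0.16 in place of -0.06 and where vehicle replicate 2 carried most of the shift (mean spike-in difference -0.22 with all arrays and -0.09 without it).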

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

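No named gene or list past the threshold changed direction under any setting, but sizes changed as well as how many passed: the median of AhR targets ran from 0.05 to 0.86 and Slc29a4 from -3.90 to -1.52. The normexp correction of median signals and the spike-in scaling were chosen after the data were seen. The planned normexp on mean signals and the slide as a block could not be run. Against 902 features (492 higher, 410 lower, 502 at least 2-fold), normexp on median signals gave 1589 (809 higher, 780 lower) with 2 lists lower in place of 4. Without a filter on dim probes 194 passed (124 higher, 70 lower, 190 at least 2-fold), with 48957 features tested in place of 29326. With treat against 0.5, a stricter null, 131 passed (90 higher, 41 lower). Median centring gave 746 higher, array weights 632 lower and spike-in scaling 130 lower; the cause was not tested. Leaving out 1 array leaves fewer samples and gave 104 to 365 features, 70 to 221 higher, 34 to 144 lower and 104 to 345 at least 2-fold, with 10 to 15 lists higher and 3 to 5 lower. By list, camera with an estimated correlation called 0 higher and 0 lower, and fry, which does not compare a list with other genes, 6 and 1, in place of 12 and 4; 6731 features had an unadjusted p under 0.05. The replicate block gave 211 features (133 higher, 78 lower, 211 at least 2-fold), of which 185 were among the 902. Same-numbered arrays shared little deviation over all features (correlations 0.00, -0.02 and 0.14, with 2 of 6 arrays correlating best with their own number). The 0.14 of replicate 3 was also the highest correlation of deviations across the groups. Correlations over so few pairs cannot show whether the numbers pair animals or mark a batch, and the cause of the lower count with the block was not tested. Over all settings, 947 of the values of named genes past the threshold stayed past it and 537 did not. Signal over background limited 44 of the 902 features, dim on all arrays of 1 group, to a bound.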

Other observations

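The genes of the next paragraphs, the Gpx2 value and the tests on spike-in probes, slides and scaling were chosen after the results were seen; the tests of other splits and of ATF4 targets were set before theirs. Of 12 tested carboxylesterases (Ces), 2 rose, Ces2c, a member of the CAR and PXR list, by 3.34 ± 0.28 and Ces2j by 2.38 ± 0.30. Of 60 Cyp genes, 11 rose and 1 fell, and Cyp2d2, in none of the lists, rose by 0.72 ± 0.13. Among 16 aldehyde dehydrogenases, the retinal-oxidizing Aldh1a1, also of the CAR and PXR list, rose by 1.44 ± 0.14 and the cytosolic folate enzyme Aldh1l1 by 1.03 ± 0.19, whereas the mitochondrial folate enzyme Aldh1l2 fell by 0.87 ± 0.16 and the proline-synthesis enzyme Aldh18a1 by 1.05 ± 0.13, with probes from -2.79 to -1.05. The aldo-keto reductase Akr1c13 fell by 1.54 ± 0.16 and the glutathione transferase Gstp3 by 1.33 ± 0.19. Gpx2, a glutathione peroxidase, had a log2 difference of 5.45 ± 1.18 that did not pass (adjusted p = 0.0657).

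Other families also held calls. The lectin-like Clec2d2l1 and Clec2d2l2, close relatives whose probes can bind RNA of each other, rose by 3.35 ± 0.58 and 3.37 ± 0.54. Of 244 solute carriers (Slc), 8 rose and 4 fell, among the latter Slc16a11 at -1.18 ± 0.23. Of 23 serpins, 2 fell, including Serpina6, the corticosteroid carrier of plasma, by 1.31 ± 0.20. None of 11 acyl-CoA thioesterases (Acot) passed.

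Atf5, Asns, Nupr1 and Phgdh, which fell, are known targets of ATF4, the transcription factor of the amino acid response, and a hypothesis is that ATF4 activity was lower with TBBC, tested on 27 further ATF4 targets in none of the lists (23 measured). Their median log2 difference was -0.38, 20 were negative, 2 fell (Cars1 by 1.18 ± 0.18 and Aldh18a1 by 1.05 ± 0.13) and none rose, and camera gave p = 1.8e-04 (p = 0.241 with an estimated correlation; fry p = 0.0332). Mthfd2 at -1.95 ± 0.41 (adjusted p = 0.0601) and Psat1 at -1.79 ± 0.39 (adjusted p = 0.0686) did not pass. The median ran from -0.43 to -0.16 over the settings, and camera lost the call only with an estimated correlation. The result may fit lower ATF4 activity, but no protein was measured. Slc7a5, another ATF4 target, was past the threshold and at least 2.45-fold higher with TBBC. It was not among the 27 targets chosen, so the absence of risers holds only for those chosen.

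The higher CAR and PXR list, median 1.44, was set against technical differences between the slides. The 8 spike-in probes above background, which passed through the same hybridisation and scan, differed between the groups by at most 0.32 in size. This argues against a hybridisation or scan difference common to all probes as the whole cause. The spike-in probes cannot show a difference between the slides that affects only some other probes. A batch of housing, RNA extraction or labelling shared by a group cannot be told apart from TBBC, since 0 slides held both groups. For the 902 features, 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05; the real split was 1 of 10 with as many calls, and the highest other split gave 5.

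The higher proteasome list and the lower ribosomal protein list were set against the scaling of the arrays. A shift of whole arrays would move all features as far as the list, but their median was -0.06 and the proteasome median 0.38, and under quantile normalization and normexp, which are no plain shifts, the list stayed 0.42 and 0.53 above the median of all features, which argues against scaling as its cause. The ribosomal protein median lay at -0.18 and -0.12 on that measure and at -0.16 in the main fit. Spike-in scaling shifts each array as a whole and cannot change that value, so its -0.16 there does not bear on the question. The level of the list itself depended on the scaling, with a median of -0.22 in the main fit and 0.00 on the spike-in controls. The call was lost on the spike-in controls (camera adjusted p = 0.0766), so the criterion set for the test, a call under every scaling, was not met. The test does not decide the question for this list. Vehicle replicate 2 carried most of the spike-in shift: its mean spike-in value was 4.48 against 3.97 to 4.17 on the other arrays, and the mean difference between the groups was -0.22 with it and -0.09 without it. TBBC and a batch shared by a group stay open and untested for both lists, whose calls were lost with an estimated correlation.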
